A study of Mus musculus with 5 samples.

How the data were processed

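Messenger RNA was measured in single cells of the mouse intestine with 10x Genomics 3' v3 libraries, per the labels' protocols, in 5 libraries with 1 per stage (E12.5, E14.5, E16.5, E18.5 and P1.5). Per the same protocols tissue was dissociated with collagenase type 1 and hyaluronidase, no cell sorting is stated, and the cells aimed for were 10000 at E12.5 and E14.5 and 5000 at the later stages. The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, and whole numbers were found throughout when the values were checked. Cell Ranger 3.1.0 with the mm10 genome build was used, per the submitters' processing notes. The settings for cell calling and the annotation release are not given in the sources used here. Each library listed 31053 Ensembl genes, of which 30934 (99.62%) were found by ID in a GENCODE annotation of GRCm38, the build of mm10, and 30468 had the same symbol there. Gene positions come from that annotation, 1-based.

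The gene lists, cell-type markers, comparisons, naming rule for genes and most alternative settings were fixed before the data were examined. Cells were kept with at least 500 detected genes and at most 20% mitochondrial UMIs. This passed 39.5% of barcodes at E12.5, 91.7% at E14.5, 80.8% at E16.5, 56.7% at E18.5 and 44.1% at P1.5. Doublets were scored within each library as the share of simulated doublets among a cell's neighbours, and the top share was removed, set at 0.8% per 1000 barcodes. This removed 870, 1168, 221, 245 and 209 cells in order of stage. Median UMIs per kept cell were 2731, 6513, 8407, 6601 and 5098. Each library was clustered on its own from log-normalised counts with 2000 variable genes, 30 principal components, 15 exact nearest neighbours and the Leiden algorithm at resolution 1, which gave 21, 24, 24, 26 and 22 clusters. Mitochondrial, ribosomal protein, globin and sex-linked genes were kept out of the variable genes.

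Cluster names were rebuilt here from fixed markers of 17 classes and are not the authors' names. A class score was the mean log2 ratio of its markers' CPM over the median of all clusters, with 10 CPM added to both. A name needed 3 markers detected in at least 10% of cells and at least 1 log2 unit over the reference, a lead of 0.5 over the next class, and no more markers of another class among the cluster's top 10 genes. A cluster whose median UMI count was more than 3-fold under that of its library also needed a marker of its class among those 10 genes. These limits of detection, ratio and lead were set after the data were seen. Clusters that failed stayed unnamed. Marker genes were left out of the ranking of named genes, and markers are printed only for globins and to describe clusters and libraries. No cluster met the naming rule for the interstitial cell of Cajal, mast cell, lymphoid, pancreatic acinar or hepatocyte class, although an unnamed E16.5 cluster of 45 cells had lymphoid as its best class. Other settings named 18 lymphoid-like cells at E16.5 (at most 10% mitochondrial UMIs) and 92 or 108 cells like interstitial cells of Cajal at E18.5 (at least 1000 genes, or Leiden resolution 2). A granulocyte-like cluster of 12 cells at P1.5 and erythroid-like clusters of 57 cells at E12.5 and 203 at E14.5 were not compared between stages.

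Within a class the counts were summed over kept cells per library and divided by the class total and scaled to 1000000, as CPM. A log2 ratio compared the later with the earlier stage. A count of 0 was set to 3 counts for a ratio, and a fold taken that way is marked as at a floor of 3 counts. Such a fold is not the limit of the counting interval, which lies closer to no change. Genes with 1 or 2 counts are given with the counting interval of the ratio. The list medians set counts under 3 to 3 and leave out genes with no more than 3 counts at both ends. Classes needed 50 cells at both ends. Intervals are 95% intervals, exact Poisson for CPM, exact conditional binomial for a ratio of counts, Clopper-Pearson for shares, and from 1000 Poisson draws for list medians, and they cover counting error only. The percentile of a list is its place among 10000 random lists, each member drawn from the 100 genes nearest in mean expression. With 1 library per stage no test between stages was made, and no paired analysis was possible because each stage came from other animals. Comparisons ran from E12.5 to P1.5 where both ends had enough cells, otherwise to the last or from the first stage that had. For epithelial-like cells E18.5 replaced P1.5, and E18.5 against E16.5 replaced P1.5 against E18.5. For myeloid-like cells E18.5 was the later stage, for neuron-like cells E16.5, and for lymphatic-endothelial-like cells E14.5 was the earlier stage. Shares of cells with a UMI are not compared, so the planned thinning to 2000 UMIs per cell was not used.

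Named genes were ranked by log2 ratio, 12 higher and 12 lower in epithelial-like, fibroblast-like and smooth-muscle-like cells and 5 and 5 in other classes. They needed at least 100 UMIs and 50 CPM at the higher end and at least 0.25 of the highest CPM of any other class of that library, as a guard against free RNA. For P1.5 against E12.5, the E18.5 value had to lie on the same side of E14.5, and for E18.5 against E12.5 the E16.5 value. This used the floor of 3 counts, and Rcan2 and Olfml2a in smooth-muscle-like cells passed only through it, with no UMI at E18.5 against 0.542 CPM each at E14.5. Markers, mitochondrial, globin and sex-linked genes and genes without a symbol of their own were left out. For each of the 29 fixed lists, among them fat absorption, brush border, cell cycle, fetal growth and globins, members with the most UMIs in the class were also named. Globin shares were taken over all barcodes of each library.

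Alternatives were at most 10% mitochondrial UMIs, at least 1000 genes, no doublets or 2 times the doublets removed, Leiden resolution 0.5 or 2, all libraries clustered together, the class of each cell's highest marker score, other totals or median-of-ratios scaling, the mean of each cell's CPM, and a floor of 10 counts. Chosen after seeing the data were the runs without a mitochondrial limit, the runs that put every cluster in its best class, and the exchanges of stage. The calculation of ratios, intervals and percentiles was tested on simulated data, with 50 genes changed at each fold size. The changed genes were well counted at both ends and the noise was counting noise alone. Genes with few counts and variation between libraries are therefore not covered. For E18.5 against E12.5 in epithelial-like cells (6343 genes) the direction was recovered for 98.0% of genes changed 1.5-fold and 100.0% of those changed 2-fold. For P1.5 against E12.5 these were 98.0% and 100.0% in fibroblast-like cells (7460 genes), and 100.0% at both sizes in smooth-muscle-like cells (4774 genes). Lists with no change lay outside the central 95% of random lists in 12.0%, 10.0% and 2.00% of draws in these 3 classes. Tools were Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and Matplotlib 3.10.9.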

Results

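Single-cell RNA-seq with 10x Genomics 3' v3 chemistry was made from the intestine of C57BL/6J mice, an inbred laboratory strain, at 5 stages that run from before villus formation to just after birth. The stages were embryonic days E12.5, E14.5, E16.5 and E18.5 and postnatal day P1.5, with 1 library each and no replicates. The E12.5 library came from 60 pooled midguts and the E14.5 library from 35, both with the dorsal mesentery attached. The E16.5, E18.5 and P1.5 libraries each came from the opened and flushed small intestine of 2 animals, so dissection differs between the early and the late stages. The libraries held 16598, 12620, 5849, 7353 and 7697 cell barcodes in order of stage, with 45668168, 94795504, 51652490, 49539720 and 34210094 unique molecular identifiers (UMIs). Median UMIs per barcode were 1209 at E12.5, 6498 at E14.5, 7301 at E16.5, 4889 at E18.5 and 3159 at P1.5. More than 20% of UMIs were mitochondrial in 55.4% of barcodes at E12.5, 5.99% at E14.5, 15.4% at E16.5, 41.4% at E18.5 and 55.5% at P1.5. After the limits on genes and mitochondrial UMIs and after doublet removal, 5685, 10405, 4507, 3925 and 3188 cells were kept. Each interval below is a 95% interval for counting error only, and each percentile or interval of a list describes these libraries, not the population of mice.

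Transcripts of the X-inactivation gene Xist and of Y-linked genes separated the libraries by sex. Over all barcodes Xist stood at 1025 CPM (UMIs scaled to a library total of 1000000) at E18.5, but at 0.136 CPM at E16.5 and 0.117 CPM at P1.5. The Y-linked gene Ddx3y ran the other way, with 45.0 CPM at E16.5, 104 CPM at P1.5 and 0 of 49539720 UMIs at E18.5. At E12.5 and E14.5 both genes were present, with Xist at 299 and 990 CPM and Ddx3y at 19.03 and 19.23 CPM. Sex therefore went with stage among the 3 late libraries.

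**Figure D1:**
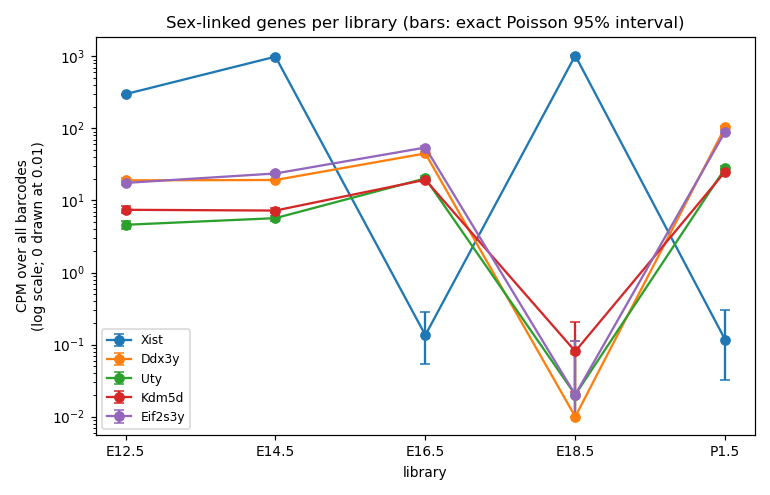
Xist and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y over all barcodes of each library, in CPM on a log axis, with exact Poisson 95% intervals and a count of 0 drawn at 0.01. The E16.5 and P1.5 libraries have under 1 CPM of Xist and carry the Y-linked genes, the E18.5 library shows the opposite, and E12.5 and E14.5 hold both.

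The first question was which cells made up the gut at each stage. Epithelial-like cells made up most of the E16.5 library, fibroblast-like cells were most frequent in the E14.5 and E18.5 libraries, and blood-endothelial-like cells held most of the E12.5 and P1.5 libraries. No kept cell of the P1.5 library was epithelial-like. Cell names were rebuilt from fixed markers, and the shares below come after the mitochondrial limit and doublet removal and carry the differences in dissection and depth. Epithelial-like cells made up 4.56% of kept cells at E12.5 (4.03 to 5.13%), 8.65% at E14.5 (8.12 to 9.21%), 65.5% at E16.5 (64.1 to 66.9%) and 16.9% at E18.5 (15.8 to 18.1%). At P1.5 their count was 0 of 3188 cells, which allows a share of up to 0.116%. At a floor of 3 counts the share was 48.4-fold lower than at E12.5 (log2 ratio -5.60, upper limit -5.12). Without the mitochondrial limit 136 of 5569 P1.5 cells were epithelial-like, and the log2 ratio was then -1.18. Fibroblast-like cells were 8.004% of cells at E12.5 (7.31 to 8.74%) and 14.0% at P1.5 (12.8 to 15.2%), a log2 ratio of 0.80 (0.55 to 1.06). With at most 10% mitochondrial UMIs that ratio was -0.90. Smooth-muscle-like cells were 13.3% at E12.5 (12.4 to 14.2%) and 4.55% at P1.5 (3.85 to 5.33%), a log2 ratio of -1.54 (-1.88 to -1.22), but the direction turned with at most 10% mitochondrial UMIs (0.0750), with 2 times the doublets removed (0.37) and with at least 1000 detected genes (0.75), where 27.8% of the E12.5 cells were unnamed. Without a mitochondrial limit the value was close to 0 (-0.00963).

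Within the midgut dissection the E14.5 over E12.5 log2 ratios of the shares were 0.92 (0.66 to 1.19) for epithelial-like, 1.64 (1.47 to 1.82) for fibroblast-like and -0.02 (-0.19 to 0.15) for smooth-muscle-like cells. Within the small-intestine dissection the P1.5 over E16.5 log2 ratios were 1.12 (0.83 to 1.41) for fibroblast-like and 1.93 (1.30 to 2.56) for smooth-muscle-like cells. Under the fixed limits the epithelial-like share was 696-fold lower at P1.5 than at E16.5 at a floor of 3 counts (log2 ratio -9.44, upper limit -9.11). It was 2.44% against 67.9% without the mitochondrial limit, and 0.376% against 66.9% with all libraries clustered together. Blood-endothelial-like cells were 59.6%, 6.93%, 0%, 18.6% and 58.3% of cells in order of stage. The 0% at E16.5 leaves out an unnamed cluster of 80 cells (1.78%, 1.41 to 2.20%) that scored close to both endothelial classes. Blood endothelial markers over all barcodes were also lowest at E16.5, at 77.8 CPM of non-mitochondrial UMIs against 545 at E14.5 and 3190 at E18.5. Myeloid-like cells were 5.73%, 6.43%, 11.6% and 15.5% of the 4 embryonic libraries and 0 of 3188 cells at P1.5. Neuron-like cells were most frequent at E14.5 (9.03%, 8.48 to 9.59%) and no cluster was named neuron-like at E18.5 or P1.5. Glia-like or progenitor-like cells were 2.76%, 9.99%, 0.843%, 5.17% and 9.32% of cells. Mesothelial-like cells peaked at E18.5 with 8.31% (7.46 to 9.21%), and lymphatic-endothelial-like cells did so with 6.55% (5.79 to 7.37%). Pericyte-like clusters were named at P1.5 alone (4.96%). Clusters left unnamed because class scores lay close together held 1.25%, 8.90%, 6.59%, 0% and 3.42% of cells, and all unnamed clusters together 1.25%, 12.4%, 10.1%, 2.62% and 4.80%.

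**Figure D2:**
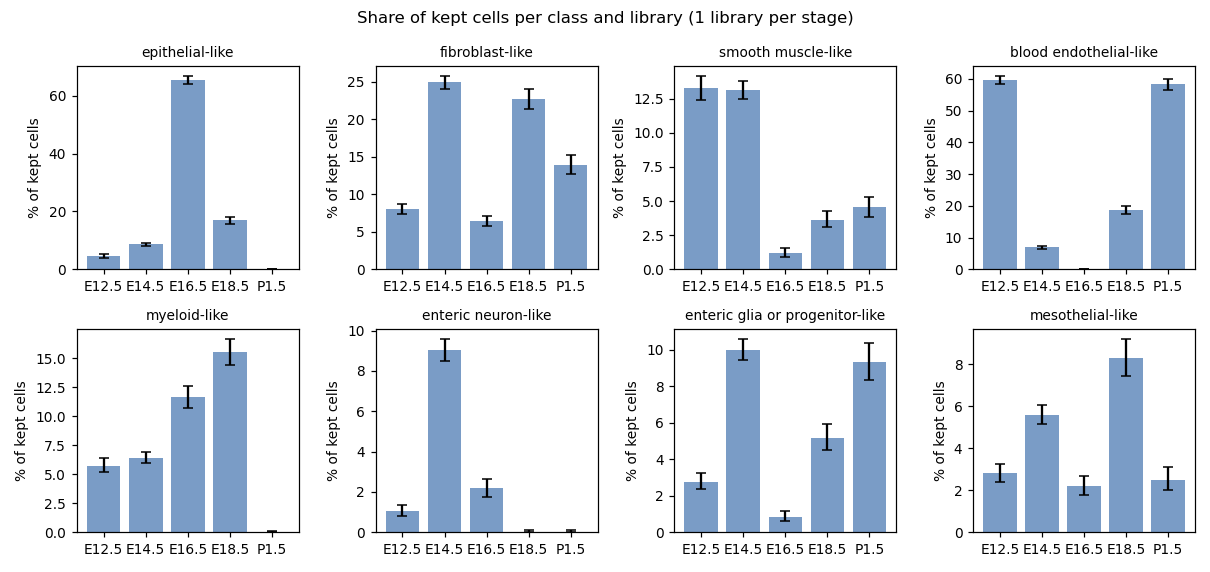
Share of kept cells (%) in 8 classes for each of the 5 libraries, with exact binomial 95% intervals as error bars. Epithelial-like cells stand at 65.5% at E16.5, and blood-endothelial-like cells at 59.6% at E12.5 and 58.3% at P1.5.

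The epithelium was compared between E12.5 and E18.5 to ask when the machinery for fat absorption appears. Genes for taking up and packaging dietary fat were far higher at E18.5, before the first milk meal, and so were brush-border enzymes, uptake into lysosomes and goblet and hormone genes. Cell-cycle genes were lower. The comparison rests on 665 epithelial-like cells at E18.5 and 259 at E12.5, which lay in different clusters, 5 at E18.5 (the largest with 380 cells) and 2 at E12.5 (the largest with 210). The median log2 ratio over all genes was -0.54 in this pair. Of the 19 fat absorption genes 18 were higher, with a median log2 ratio of 5.50 (5.39 to 6.09; percentile 100.0 among random lists of like expression), and their sum was 71765 CPM at E18.5 against 415 CPM at E12.5. Fabp2 (ENSMUSG00000023057; chromosome 3, 122895072 to 122899506, GRCm38), which encodes the intestinal fatty-acid-binding protein, stood at 25464 CPM (25340 to 25589) against 49.99 CPM (39.5 to 62.4). Fabp1, its liver-type relative, stood at 15358 CPM against 24.4 CPM (log2 ratio 9.30, 8.84 to 9.80). Apoa4 (ENSMUSG00000032080, chromosome 9, 46240696 to 46243459), an apolipoprotein of chylomicrons, had 7931 CPM at E18.5 and no UMI at E12.5. It was 4125-fold higher at a floor of 3 counts, with a log2 ratio of at least 11.71. Apoc3 had 3551 CPM against 0.641 CPM, the latter from 1 UMI, so its log2 ratio lay between 9.96 and 17.74. Apoa1 (8704 against 84.6 CPM) and the retinol carrier Rbp2 (6268 against 14.7 CPM) were higher too. The sialic acid lyase Npl, the mitochondrial creatine kinase Ckmt1, the guanylate cyclase ligand Guca2b and the lectin Clec2h were also among the 12 genes with the largest higher ratios.

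**Figure D3:**
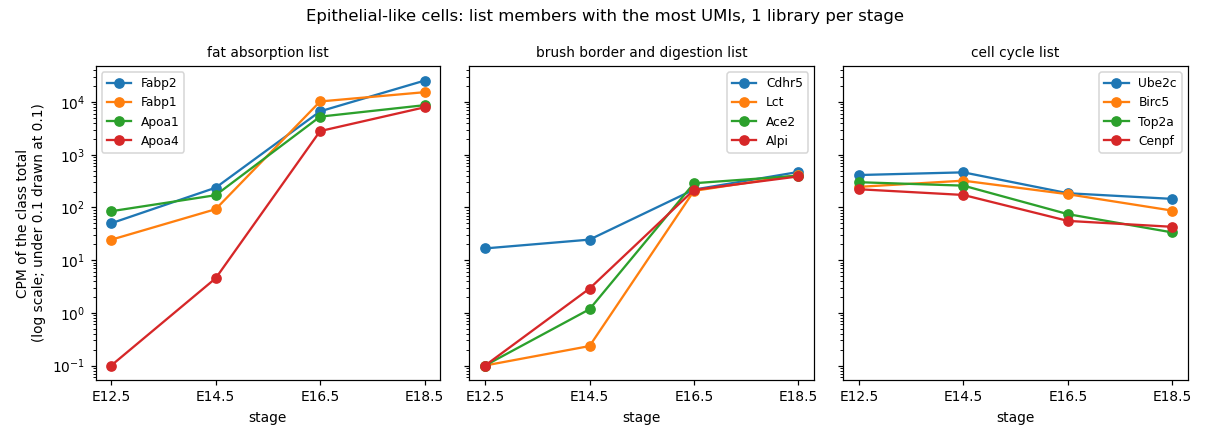
CPM of summed epithelial-like cells at E12.5, E14.5, E16.5 and E18.5 on a log axis (values under 0.1 drawn at 0.1), for the 4 members with the most UMIs of the fat absorption, brush-border and cell-cycle lists, 1 library per stage. Fabp2 stands at 49.99 CPM at E12.5 and 25464 CPM at E18.5, and the cell-cycle genes are lower at E18.5 than at E12.5.

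Digestive, lysosomal and metabolic programs went the same way in this pair. The brush-border list had a median log2 ratio of 5.06 (4.73 to 5.33; 19 of 20 genes higher), with lactase (Lct) at 412 CPM and alkaline phosphatase (Alpi) at 388 CPM against no UMI for either at E12.5. The neonatal Fc receptor Fcgrt, which carries maternal antibody across the gut wall, stood at 1497 against 4.49 CPM, and all 12 endocytosis and lysosome genes were higher (median 2.47, 2.32 to 2.74). The neonatal metabolism list had a median of 3.91 (3.74 to 4.47), with the urea-cycle genes Ass1 at 1472 against 19.2 CPM and Cps1 at 691 against 32.1 CPM. Interferon-response genes were higher in all 10 members (median 3.57, 3.42 to 3.96), and the glucocorticoid list stood at 1.00 (0.35 to 1.46). The goblet list had a median of 5.88 (5.70 to 6.08), with Tff3 at 2166 against 32.7 CPM, Agr2 at 1532 against 1.92 CPM and Spink4 at 1495.5 CPM against no UMI. These 3 genes were among the top genes of 1 cluster of 47 of the 665 cells. The enteroendocrine list stood at 4.03 (3.83 to 4.17). The gut hormone neurotensin (Nts, ENSMUSG00000019890, chromosome 10, 102481756 to 102490486) stood at 6774 CPM against no UMI, 3523-fold higher at a floor of 3 counts. Secretin (Sct) stood at 4253 against 48.1 CPM, and both genes were among the top genes of 1 cluster of 33 of the 665 cells. That list's direction turned when 2 times the expected doublets were removed (-0.06) and when all libraries were clustered together (-0.07). Paneth and antimicrobial genes stood at 1.74 (1.38 to 2.01; 7 of 8 genes higher), and Defa24 (199 CPM against no UMI) made up most of their sum of 263 CPM. Tuft genes were near the detection limit (7.27 against 1.92 CPM for the sum; median -1.44, positive under 2 other settings). Gastric genes stood at 0.48 (-0.44 to 1.04), led by Tff1 at 162 against 19.2 CPM.

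Growth programs of the early epithelium were lower at E18.5. All 20 cell-cycle genes were lower, with a median log2 ratio of -2.19 (-2.47 to -2.06), such as Top2a at 33.5 against 301 CPM. The stem and Wnt list stood at -1.02 (-1.35 to -0.65; percentile 9.41), closer to the all-gene median, with Sox9 at 25.9 against 147 CPM. The fetal epithelium list stood at -1.54 (-2.51 to -0.94), with the Hedgehog ligand Shh at 5.53 against 263 CPM and the transcription factor Sox11 at 4.90 against 303 CPM. The growth factor midkine (Mdk) had the largest lower ratio, 6.95 against 2601 CPM (log2 ratio -8.55, -9.01 to -8.12). Threonine dehydrogenase (Tdh) had no UMI at E18.5 against 116 CPM and was 245-fold lower at a floor of 3 counts. Pth1r, Gjc1, Kcnk2, Kcnq3, Tead2, Palm3, Ltbp1, Pla2g1b and Vcan completed the 12 lower genes. The fetal growth list had a median of -1.62 (-1.74 to -1.41), yet its summed expression was 5609 CPM against 4787 CPM, because H19 (2745 against 1181 CPM) and Cdkn1c (2165 against 399 CPM) were higher. Hypoxia and glycolysis genes (-0.24, -0.30 to -0.18) lay above the all-gene median of this pair and turned positive with median-of-ratios scaling (0.31). Immediate early genes stood at -0.37 (-0.70 to 0.01), an interval that includes that median.

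On a log scale most of the fat absorption difference lay between E14.5 and E16.5, where the dissection also changes. At E14.5 the list was higher than at E12.5 by a median of 0.76 (0.54 to 1.09; all-gene median -0.20), and its sum was 831 CPM, while the cell-cycle list stood at -0.11 (-0.21 to 0.01). At E16.5 the sum was already 31801 CPM, with Fabp1 at 10239 CPM and Fabp2 at 6655 CPM. From E16.5 to E18.5 the fat absorption list differed by 0.58 (0.58 to 0.60; 17 of 19 genes higher), brush-border genes by 0.91 (0.79 to 0.95), endocytosis and lysosome genes by 0.48 (0.41 to 0.55) and neonatal metabolism genes by 0.77 (0.72 to 0.84). Goblet genes were higher by 1.87 (1.79 to 1.99), Paneth and antimicrobial genes by 2.10 (1.34 to 2.51) and interferon-response genes by 3.91 (3.73 to 4.20). Cell-cycle genes were lower by a median of -0.99 (-1.13 to -0.91), hypoxia and glycolysis genes by -0.43 (-0.59 to -0.29) and fetal epithelium genes by -0.75 (-1.02 to -0.49), the last turning to 0.51 when no doublets were removed. The stem and Wnt list stood at 0.08 (-0.16 to 0.36), and at -0.07 with every cluster in its best class. Ileal bile-acid-binding protein Fabp6 (751 against 8.66 CPM), creatine-synthesis enzyme Gatm (290 against 2.41 CPM), sucrase-isomaltase Sis (75.8 against 0.111 CPM) and the stomach-type genes Tff1, Tff2 and Pga5 were among the higher genes. The metallothioneins Mt2 (11.4 against 270.1 CPM) and Mt1 (519 against 2702 CPM) had the largest lower ratios, followed by Gsta1, Emid1, Nme4, Hspd1, Hmga2, Nolc1, Gstp1, Plod2, Siva1 and Hmgn1. Enteroendocrine genes were higher by 5.90 (5.44 to 6.17), with Nts at 6774 against 0.996 CPM, Pyy at 1400.0 against 0.857 CPM, and Gip, Cck, Chga and Scg2 also higher, of which Gip turned lower under 2 other settings. This depended on cluster naming. The 157 E16.5 cells (3.48%) whose best class was epithelial but were left unnamed include a cluster of 88 with Gcg, Ghrl and Cck among its top genes. With every cluster put in its best class, which also adds 72 E18.5 cells, the enteroendocrine list median was 0.20 (0.17 to 0.61). Cck was then 579 against 423 CPM, Nts 5562 against 72.3 CPM and Sis 62.3 against 5.43 CPM.

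The fixed comparison of epithelium across birth had no value under the cell limits, since no kept P1.5 cell was epithelial-like. It was therefore made without the mitochondrial limit and over non-mitochondrial counts, a choice made after the data were seen, on 136 P1.5 barcodes whose median mitochondrial share was 67.6%. In the same run that share was 21.35% in epithelial-like barcodes at E18.5 and 16.4% at E12.5. Damage to the P1.5 cells therefore cannot be told apart from stage in the values that follow. Fat absorption genes were higher at P1.5 than at E12.5 (median log2 ratio 4.33, 3.95 to 4.56; 18 of 18 genes) but lower than at E18.5 (-2.15, -2.64 to -1.93; 16 of 19 genes lower). Their sum was 8908 CPM at P1.5, 96278 CPM at E18.5 and 475 CPM at E12.5. The cell-cycle list was lower at P1.5 than at E12.5 (-1.63, -1.82 to -1.29; 18 of 20 genes lower).

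Fibroblast-like cells were compared between E12.5 and P1.5 to ask how the mesenchyme differs. Matrix genes and Hedgehog targets were higher at P1.5, and Clec3b, Dpt and Mfap5 were among the genes with the largest higher ratios. The fetal chromatin gene Hmga2 and the transcription factor genes Isl1 and Hand1 were lower. The 455 cells at E12.5 lay in 3 clusters (the largest with 350 cells) and the 445 cells at P1.5 in 2 (the largest with 414). Tac2, Isl1 and Unc5c were among the top genes of the cluster of 350, and Clec3b, Mfap5 and Itih5 among those of the cluster of 414. Unnamed P1.5 clusters of 89 and 20 cells that scored close to both fibroblast and smooth muscle lay outside the class. Whether the class holds the same kind of fibroblast at both stages was not tested. Matrix maturation genes were higher by a median of 2.24 (2.16 to 2.44; 10 of 12 genes), with Col14a1 at 1273 against 117 CPM and the microfibril protein Mfap5 at 1103 against 3.87 CPM (log2 ratio 8.16, 7.40 to 9.03). Hedgehog response genes were higher by 3.63 (3.17 to 3.99; 5 of 6 genes), with the transcription factor Gli1 at 92.3 against 2.76 CPM and the receptor Ptch1 at 77.4 against 16.8 CPM. Tetranectin (Clec3b, ENSMUSG00000025784; chromosome 9, 123150946 to 123157432) stood at 625 CPM against 0.276 CPM, from 1 UMI, a log2 ratio between 8.66 and 16.45. Dermatopontin (Dpt) stood at 209 against 0.829 CPM, and the transporter Abca8a, with no UMI at E12.5, was 252-fold higher at a floor of 3 counts. Fndc1, Col5a3, Entpd2, Fmo2, Ifi27l2a, Itih5, C1s1 and Nov completed the 12 higher genes. Hmga2 (ENSMUSG00000056758; chromosome 10, 120361275 to 120476469) was lower, at 2.74 against 441 CPM (log2 ratio -7.33, -8.95 to -6.10), as were Isl1 (2.74 against 192 CPM), Hand1 (2.20 against 69.0 CPM), the neurokinin gene Tac2 and the chemokine Cxcl13. Kif26b, Shisa2, Col8a1, Rprm, Speg, Unc5c and Sptssb completed the 12 lower genes.

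The fibroblast-like signals and growth programs differed less uniformly. The Wnt and BMP-antagonist list stood at 0.95 (0.73 to 1.43), with Cd34 at 366 against 26.0 CPM but Rspo3 at 26.4 against 95.8 CPM. Villus mesenchyme signals stood at -0.36 (-0.90 to 0.00; percentile 8.34), with Wnt5a higher (174 against 34.3 CPM) and Bmp4 lower (5.49 against 45.6 CPM). Cell-cycle genes were lower in all 20 members (median -1.03, -1.22 to -0.83). Most of their UMIs came from small clusters, 74 of 455 cells at E12.5 with 7697 CPM and 31 of 445 at P1.5 with 7985 CPM. The largest clusters differed in the same direction, at 1014 CPM in 350 cells at E12.5 and 356 CPM in 414 cells at P1.5. With 2 times the expected doublets removed the E12.5 sum was 847 rather than 2233 CPM and the median turned to 0.21. The fetal growth list stood at -0.34 (-0.55 to -0.27), at percentile 46.7 of random lists, and at 0.0629 with E14.5 in place of E12.5. Its abundant imprinted members went both ways between E12.5 and P1.5, with H19 at 3257 against 1411 CPM and Cdkn1c at 1383 against 2592 CPM. Contractile genes stood at -0.49 (-0.69 to -0.10) and turned positive under 3 settings. Interferon-response genes (2.71, 2.08 to 3.20), glucocorticoid-response genes (1.33, 0.92 to 1.78) and immediate early genes (1.45, 0.99 to 2.31) were higher, the last with Egr1 at 302 against 15.5 CPM. Hypoxia and glycolysis genes were lower (-1.15, -1.51 to -0.88), with Ldha at 129 against 349 CPM.

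Smooth-muscle-like cells were compared between the same stages to ask whether the contractile apparatus matured. Contractile and matrix genes were higher at P1.5, and fetal growth genes and targets of Hedgehog signalling were lower. At P1.5 the class was 1 cluster of 145 cells with the vascular mural gene Notch3 at 776 CPM, and a separate unnamed P1.5 cluster of 44 cells carried Actg2 at 1513 CPM with Kit at 830 CPM and Etv1 at 863 CPM. At E12.5 it was 2 clusters of 754 cells. The larger, of 534 cells, had a median of 1457.5 UMIs, fibroblast as its next class and no class marker among its top 10 genes. With all libraries clustered together 91 E12.5 cells were smooth-muscle-like. At E18.5 the class was 1 cluster of 143 cells with Actg2, Kit and Etv1 among its top 10 genes, so the class may not hold the same cells at each stage. The all-gene median log2 ratio was 0.17. Contractile maturation genes were higher by a median of 2.28 (2.04 to 2.43; 15 of 18 genes), with Tpm2 at 3159 against 579 CPM and Csrp1 at 1014 against 139 CPM. The value was 1.36 with at least 1000 detected genes per cell and 1.44 (0.92 to 1.75) in the P1.5 cluster of 44 cells. Elastin (Eln, ENSMUSG00000029675; chromosome 5, 134702593 to 134747323), the rubber-like protein of artery walls, was highest by ratio, at 7781 against 9.18 CPM (log2 ratio 9.73, 9.13 to 10.40). The matrix list stood at 2.36 (2.10 to 2.81), with Col4a1 at 2038 against 160 CPM. Igfbp7 (2589 against 4.59 CPM), Mcam (1275 against 10.0 CPM), Aoc3, Aspn, Mustn1, Inpp4b, Rcan2, Pfkp, Tinagl1, Olfml2a and Crip1 completed the 12 higher genes.

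Lower genes in smooth-muscle-like cells again began with Hmga2 (4.31 against 837 CPM; log2 ratio -7.60, -9.48 to -6.24). Neuronatin (Nnat), the activin antagonist follistatin (Fst, no UMI against 310 CPM, 95.8-fold lower at a floor of 3 counts), pleiotrophin (Ptn, 14.0 against 1042 CPM), Sfrp1, the retinoic-acid enzymes Aldh1a2 and Aldh1a1, Phgdh, Zfhx4, Dlk1, Mpped2 and Col23a1 followed. Several of these ratios were much smaller when every cluster was put in its best class, with Ptn at 226 against 1042 CPM and log2 ratios of -1.86 for Sfrp1 and -2.10 for Aldh1a1 rather than -6.14 and -5.25. The fetal growth list stood at -2.09 (-2.44 to -1.91), with Cdkn1c at 92.7 against 1976 CPM. Hedgehog response genes stood at -1.78 (-2.41 to -1.29; 6 of 6 lower) and Wnt and BMP-antagonist genes at -2.22 (-2.40 to -1.61). With every cluster in its best class the fetal growth, Hedgehog and Wnt lists stood at -1.18 (-1.42 to -1.04), -0.78 (-1.17 to -0.11) and -0.52 (-1.18 to -0.19). Cell-cycle genes were lower in all 20 members (-0.85, -1.17 to -0.75), and immediate early genes were higher (2.42, 1.82 to 2.95).

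**Figure D4:**
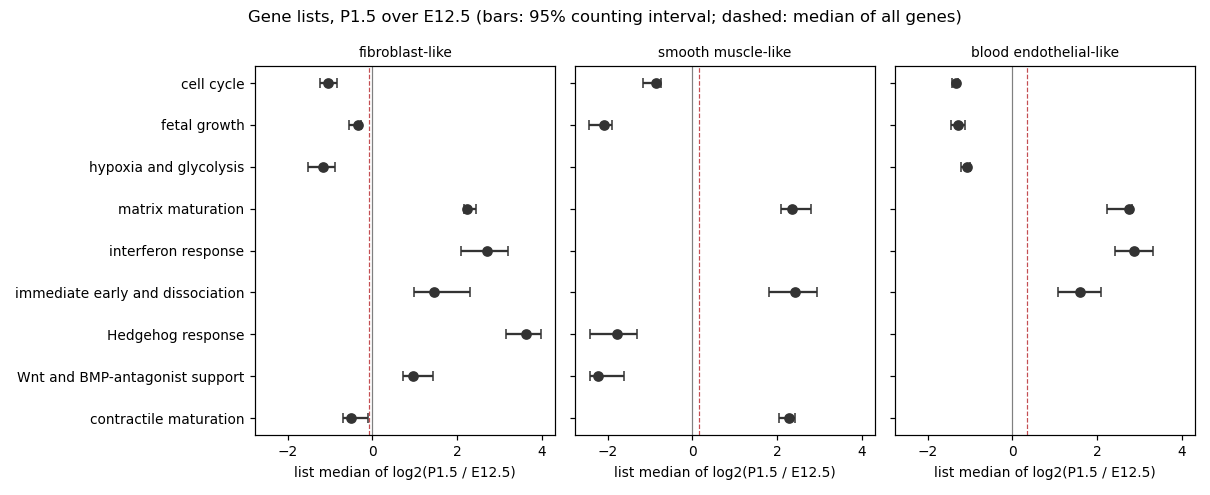
Median log2 ratio, P1.5 over E12.5, of gene lists in fibroblast-like, smooth-muscle-like and blood-endothelial-like cells, with 95% counting intervals as bars, the median of all genes as a dashed line and a point only for lists reported in that class. Hedgehog response genes stand at 3.63 in fibroblast-like and -1.78 in smooth-muscle-like cells, and matrix genes stand above 2 in each of the 3 classes.

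Blood-endothelial-like cells (3388 at E12.5 in 8 clusters and 1858 at P1.5 in 9) carried more matrix, fat-handling and sprouting transcripts at P1.5 and fewer cell-cycle transcripts. Capillary endothelium moves fatty acids into tissue, and of that list Fabp4 stood at 4460 against 1206 CPM and Gpihbp1, the anchor of lipoprotein lipase, at 452 against 166 CPM, while Fabp5 and Tcf15 were lower. Its median was 1.89 (1.81 to 1.91; 6 of 9 genes higher), against an all-gene median of 0.33. Sprouting genes stood at 1.57 (1.41 to 1.62), with the tip-cell gene Esm1 at 234 against 79.0 CPM, and matrix genes at 2.75 (2.23 to 2.83), with Col4a1 at 4149 against 921 CPM. Interferon-response genes (2.87, 2.42 to 3.33) and immediate early genes (1.61, 1.09 to 2.10) were higher. Cell-cycle genes (-1.34, -1.42 to -1.28), fetal growth genes (-1.27, -1.44 to -1.12) and hypoxia and glycolysis genes (-1.07, -1.20 to -1.01) were lower. Igfbp7 (ENSMUSG00000036256; chromosome 5, 77349240 to 77408041) was highest by ratio, at 6930.0 against 11.2 CPM, followed by Scgb3a1, angiotensin-converting enzyme (Ace), Lrg1 and Mctp1. Ly6h, Nme4, Igf2bp1, Myh10 and Mif were the 5 lower genes. In lymphatic-endothelial-like cells (257 at E18.5 in 2 clusters, the largest with 139, and 105 at E14.5 in 1) fat-handling genes were higher (1.12, 1.02 to 1.65), with Lpl at 122 against 5.47 CPM. Sprouting genes stood at -0.89 (-1.12 to 0.04) and cell-cycle genes at -0.65 (-0.76 to -0.55). Klrb1f (among the top 10 genes of the cluster of 139 alone), Cp, Pdlim3, Thbs1 and Neat1 were the higher genes there, and AY036118, Hpgd, Dctpp1, Ptp4a3 and Ltb the lower ones.

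Glia-like or progenitor-like cells (157 at E12.5 and 297 at P1.5) carried more matrix transcripts and fewer cell-cycle transcripts at P1.5. The chaperone Cryab stood at 1086 CPM against no UMI at E12.5, 245-fold higher at a floor of 3 counts. Col14a1, Sostdc1 and Matn2 were also among the higher genes. The matrix list stood at 3.44 (2.65 to 3.61), cell-cycle genes at -1.33 (-1.49 to -1.14) and hypoxia and glycolysis genes at -1.22 (-1.67 to -0.57). Hmga2 was lower here too (11.02 against 457 CPM), with Arhgap28, Hist1h1b, Ppa1 and Ube2c. In neuron-like cells (59 at E12.5 and 98 at E16.5) the transmitter list stood at 0.38 (-0.38 to 0.69), an interval that includes 0, while its sum was lower at E16.5 (1712 against 4045 CPM). The neurofilament genes Nefm (53.6 against 2346 CPM) and Nefl (149 against 2385 CPM) and the noradrenaline-synthesis gene Dbh were lower at E16.5, with Ntng1 and Onecut2, and Nfib, Serpine2, Ass1, Chodl and Ldha were higher. The cell-cycle list there stood at -0.84 (-1.51 to -0.26) but at 1.05 with Leiden resolution 0.5.

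Mesothelial-like cells (159 at E12.5 and 80 at P1.5) had higher matrix and interferon-response genes at P1.5. Complement component C3 stood at 3768 against 0.741 CPM, from 1 UMI. The protease inhibitor Slpi stood at 1940 CPM against no UMI, 873-fold higher at a floor of 3 counts. Nupr1, Dmkn and Ifi27l2a followed. The matrix list stood at 2.38 (1.78 to 3.12), interferon-response genes at 2.45 (1.90 to 3.41) and the fetal epithelium list, whose members Anxa1 and Clu mesothelium also carries, at 3.71 (2.95 to 4.09). Hmga2 (7.65 against 643 CPM), Nme4, Tspan12, Cnih2 and Fxyd7 were lower, and the fetal growth list stood at -0.94 (-1.14 to -0.69). The cell-cycle list stood at 0.47 (-0.15 to 0.59), although its sum was 909 against 1190 CPM.

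Myeloid-like cells (326 at E12.5 in 1 cluster and 608 at E18.5 in 4) carried antigen-presentation genes at E18.5 that were nearly absent at E12.5. All 5 MHC class II genes were higher, with a median log2 ratio of 10.14 (9.11 to 10.17) and a sum of 12327 against 20.8 CPM. That median is the ratio of H2-Eb1, which had no UMI at E12.5, so it and its interval depend on the floor of 3 counts. H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) stood at 2457 CPM with no UMI at E12.5, 1651-fold higher at a floor of 3 counts. The invariant chain Cd74 stood at 6246 against 19.4 CPM, and H2-Ab1, H2-Eb1 and the gut macrophage gene Adamdec1 were also among the 5 higher genes. The resident macrophage list was lower by a median of -0.40 (-0.52 to -0.27), with 3 of 7 genes higher and 4 lower. The mannose receptor Mrc1, a lower member, stood at 422 against 1275 CPM, and the all-gene median was -0.12. Mrc1 and Pf4 were among the top 10 genes of the E12.5 cluster and of an E18.5 cluster of 95 cells. MHC class II genes were among those of E18.5 clusters of 368 and 111 cells. Whether the class holds the same kinds of myeloid cell at both stages was not tested. Interferon-response genes were higher (2.39, 2.20 to 2.65) and cell-cycle genes lower (-0.83, -0.91 to -0.69). Lars2, Hist1h1a, AY036118, Hist1h1d and Lpl were the 5 lower genes.

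Globin transcripts gave a clock of the blood in each library, since red cells of yolk-sac origin carry embryonic globins and later red cells do not. The embryonic genes Hbb-bh1, Hbb-y and Hba-x made up 81.9% of globin UMIs at E12.5 (81.8 to 82.0%; 514949 of 628600), 44.1% at E14.5 (43.9 to 44.4%) and 5.24% at E16.5 (4.96 to 5.52%). They made up 0.0385% at E18.5 (0.0232 to 0.0601%, 19 of 49368) and 0 of 5839 UMIs at P1.5, which allows up to 0.0632%. The fetal-adult genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt made up the rest.

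**Figure D5:**
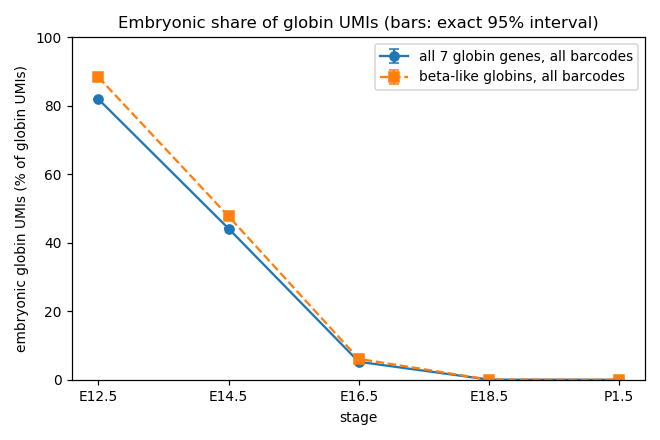
Share of globin UMIs from the embryonic globin genes (%) over all barcodes of each library, for all 7 globin genes and for the beta-like genes alone, with exact binomial 95% intervals. Over all 7 genes the share is 81.9% at E12.5, 44.1% at E14.5 and 5.24% at E16.5, and lies near 0 at E18.5 and P1.5.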

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

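The tests of the missing P1.5 epithelium and of shallow E12.5 barcodes were chosen after the result was seen, and the free endothelial RNA test and both smooth muscle tests were written before theirs.

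The P1.5 library held no epithelial-like cell under the fixed limits, yet 136 of 5569 cells (2.44%, 2.05 to 2.88%) were epithelial-like without the mitochondrial limit, in barcodes that the fixed comparisons leave out. If the limit had removed the epithelium, dropping it should restore a share near that of E18.5. The P1.5 share was 0.0850 of the E18.5 share taken the same way (0.0686 to 0.105; 2.44% against 28.7%), which argues against the limit as the whole cause. Epithelial markers over all deposited P1.5 barcodes stood at 0.0809 of their E18.5 level (0.0784 to 0.0835, 150.4 against 1858 CPM over non-mitochondrial UMIs). This argues against many intact epithelial cells in unnamed clusters or discarded barcodes. Damaged cells cannot be judged this way, since epithelial-like P1.5 barcodes without the limit had a median mitochondrial share of 67.6%. Loss of epithelial cells between tissue and droplets may still be a source, since free RNA of Fabp1, Fabp2, Apoa4, Apoc3 and Rbp2 in blood-endothelial-like cells was 0.175 of the E18.5 level (0.163 to 0.188; 70.7 against 404 CPM), a value that lies between the bounds set for and against it, and a difference of stage was not tested.

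Blood-endothelial-like cells were 59.6% of kept cells at E12.5 and 6.93% at E14.5 from the same dissection. Free endothelial RNA in droplets of other cells cannot be told apart from endothelial cells here. Endothelial markers in the 2777 cells of shallow endothelial-like clusters were 11.1 times (9.78 to 12.6) those in 534 smooth-muscle-like cells of like depth (2843 against 257 CPM), but the clusters were named from the same markers, which largely fixed that value. Shallow barcodes counted as cells cannot be told apart either, as the share depended on naming. Among the 3746 cells with at least 1000 detected genes, clustered anew, it was 34.5% (32.9 to 36.0%), but 1041 of these cells were unnamed, of which 762 had been endothelial-like before. With the earlier names kept it was 55.0% (53.3 to 56.7%) of 3460 such cells. A difference between the stages remains open and was not tested.

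List medians, P1.5 over E12.5, went in opposite directions in fibroblast-like and smooth-muscle-like cells for 4 lists, and the differences were not tested since each class has 1 library per stage. Fibroblast-like minus smooth-muscle-like medians differed by 5.41 for Hedgehog response (3.63 and -1.78), 3.17 for Wnt and BMP-antagonist support (0.95 and -2.22), 3.05 for goblet genes (1.29 and -1.76) and -2.78 for contractile maturation (-0.49 and 2.28). The goblet list was made for epithelial cells. Its medians in these 2 classes were not checked against free RNA or low counts, nor under other settings, so no change is read from them. The fibroblast-like contractile median was positive with no doublets removed (0.0457), with 2 times the doublets removed (0.0293) and with every cluster in its best class (0.18), so that contrast in direction is not stable. In the best-class run the Wnt medians were 1.42 and -0.52 and the Hedgehog medians 3.66 and -0.78. A candidate explanation for the smooth muscle side is that the class holds vascular muscle at P1.5 and gut-wall muscle at E12.5. It cannot be told apart from maturation, for the 12 genes named as higher in that class or for the contractile list. The 12 genes were lower in a P1.5 cluster of 44 cells with Kit and Etv1 than in the P1.5 smooth-muscle-like cluster of 145 cells (median log2 ratio -3.88, -4.11 to -3.55), past the bound set for the explanation. This decides nothing, because the genes were chosen for high values in the cluster of 145 cells and the cluster of 44 is not shown to be gut-wall muscle. In the cluster of 44 the contractile list was higher than in E12.5 smooth-muscle-like cells (1.44, 0.92 to 1.75), an interval too wide to choose between them beside the reported 2.28. For the other lists the explanation was not tested.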

How the results depend on the processing

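Of the 1838 values of 156 named-gene results under other settings, 1836 kept their direction and 1516 stayed within the counting interval of the reported value. These genes were chosen for the largest ratios in the same libraries, so a kept direction was likely in advance. Of the 841 values of 70 other list results, 810 kept their direction and 582 stayed within that interval, and 21 of the 31 changes of sign were in 7 lists whose reported interval includes 0. One of these was the stem and Wnt list (E18.5 over E16.5; reported as 0.08), at -0.0728 with every cluster in its best class. For the 7 lists and 3 share ratios that answer the comparisons, 64 of 66 and 30 of 36 values kept their direction. The exchanges of stage, the runs without a mitochondrial limit and those with every cluster in its best class were chosen after seeing the data. Where no cause is named, the cause was not tested.

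Share ratios (log2, P1.5 over E12.5) depended on the cell limits. For epithelial-like cells the reported -5.60 was taken at a floor of 3 counts from 0 of 3188 P1.5 cells. With at most 10% mitochondrial UMIs it was -3.53, where the same floor applied to 0 of 632 cells. The value was -3.55 with all libraries clustered together, -3.44 by highest marker score, -1.18 without a mitochondrial limit, and 1.89 with E18.5 in place of P1.5. For fibroblast-like cells, reported as 0.80, it was -0.90 with at most 10% mitochondrial UMIs, 0.22 with at least 1000 genes, 1.06 with no doublets removed, 1.44 with 2 times the doublets removed, 1.25 at resolution 0.5, 1.30 by highest marker score, 1.84 without a mitochondrial limit, 1.07 with every cluster in its best class, -0.84 with E14.5 in place of E12.5 and 1.50 with E18.5 in place of P1.5. For smooth-muscle-like cells, reported as -1.54, it was 0.0750 with at most 10% mitochondrial UMIs, 0.75 with at least 1000 genes, 0.37 with 2 times the doublets removed, -0.92 at resolution 2, -4.09 with all libraries clustered together, -0.75 by highest marker score, -0.00963 without a mitochondrial limit and -1.02 with every cluster in its best class.

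In epithelial-like cells the fat absorption list at E18.5 (5.50) was 6.27 with no doublets removed, 5.22 with 2 times the doublets removed, 5.38 without mitochondrial, ribosomal protein and globin genes in the total, 5.33 with a floor of 10 counts and 6.44 without a mitochondrial limit. At P1.5, without that limit, the list (4.33) was 3.55 with median-of-ratios scaling. Across birth (-2.15) it was -2.89 with that scaling and -1.78 with the mean of each cell's CPM. The cell cycle list (-1.63) was -1.83 without mitochondrial, ribosomal protein and globin genes in the total, -2.40 with median-of-ratios scaling and -0.91 with a floor of 10 counts. In fibroblast-like cells the cell cycle list (-1.03) was 0.21 with 2 times the doublets removed and -0.0420 at resolution 0.5, where the E12.5 sum was 847 and 990.4 CPM rather than 2233 CPM, and -1.26 with the mean of each cell's CPM and -0.77 with E18.5 in place of P1.5. The fetal growth list there (-0.34) was -0.27 with at least 1000 genes, -0.25 with median-of-ratios scaling, 0.0629 with E14.5 in place of E12.5 and -0.23 with E18.5 in place of P1.5. The contractile list in smooth-muscle-like cells (2.28) was 1.36 with at least 1000 genes, 1.76 with 2 times the doublets removed, 2.58 with the mean of each cell's CPM, 1.39 with E14.5 in place of E12.5 and 1.46 with E18.5 in place of P1.5. The E18.5 class was a cluster of 143 cells with Kit and Etv1 among its top genes, unlike the P1.5 class.

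The embryonic globin share was 86.6% at E12.5, 41.6% at E14.5, 2.15% at E16.5 and 0.0221% at E18.5 over barcodes that passed the cell limits. It was 83.5%, 44.8%, 6.22% and 0.00601% where globins made up most of a barcode's UMIs, and 88.3%, 47.7% and 6.09% for the 3 earliest stages with beta-like globins alone.

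Other results with an interval that leaves out 0 reversed as follows. In epithelial-like cells the enteroendocrine list (E18.5 over E12.5) was -0.0601 with 2 times the doublets removed and -0.0722 with all libraries clustered together, the tuft list 0.35 with at least 1000 genes and 0.0654 with 2 times the doublets removed, the hypoxia list 0.31 with median-of-ratios scaling and the fetal epithelium list (E18.5 over E16.5) 0.51 with no doublets removed. Gip in epithelial-like cells, E18.5 over E16.5, was -0.98 with 2 times the doublets removed and -1.01 with all libraries clustered together. The contractile list in fibroblast-like cells was 0.0457 with no doublets removed, 0.0293 with 2 times the doublets removed and 0.18 with every cluster in its best class, and the neuron-like cell cycle list 1.05 at resolution 0.5. No value could be had, with under 50 cells, at 10% mitochondrial UMIs for lists of epithelial-like cells at E18.5 and of fibroblast-like, smooth-muscle-like, glia-like, mesothelial-like and neuron-like cells, with joint clustering for smooth-muscle-like and glia-like cells, with 2 times the doublets removed for glia-like and neuron-like cells, and with at least 1000 genes for neuron-like cells.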

Other observations

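No test in this part was planned, and the values below were looked up after the results were seen.

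Markers of classes for which no cluster was named were counted over all barcodes of each library, as CPM over non-mitochondrial UMIs. Interstitial cell of Cajal markers stood at 127, 128, 46.6, 195 and 323 in order of stage. Lymphoid markers stood at 13.5, 13.8, 13.1, 27.9 and 6.64, and mast cell markers at 0.671, 1.88, 0.924, 0.195 and 0.225. Pancreatic acinar markers stood at 9.11, 22.0, 60.8, 58.9 and 10.5, and hepatocyte markers, part of which the intestinal epithelium also expresses, at 40.9, 61.4, 376, 333 and 6.19. Myeloid markers stood at 2648 at E18.5 and 88.1 at P1.5, where no cluster was named myeloid-like. Neuron markers stood at 683, 1602, 185, 251 and 242 in order of stage. They were thus lower at E16.5, where 98 cells were named neuron-like, than at E18.5 and P1.5, where no cluster was.

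When all libraries were clustered together without correction, 6 of 38 clusters drew more than 90% of their cells from 1 library. Interferon-response genes had a higher median at the later stage in each of the 5 classes for which that list is reported between E12.5 and the last stage. Values of that list in other classes, such as smooth-muscle-like and glia-like cells, are not given, so this does not cover all classes. Hmga2 was among the 12 or 5 lower genes at P1.5 in fibroblast-like, smooth-muscle-like, glia-like and mesothelial-like cells but not in blood-endothelial-like cells.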
